A study of Homo sapiens with 6 samples.

How the data were processed

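RNA from BeWo cells was measured by sequencing in 6 libraries, 3 from cells given vehicle (control) and 3 from cells given soluble fms-like tyrosine kinase 1 (sFlt-1). BeWo is an established human choriocarcinoma line used as a model of placental trophoblast. Per the labels' protocols, cells were kept in 1% serum for 24 h and then exposed to sFlt-1 at 1 ng/mL for 72 h, and libraries were made from total RNA with the NEBNext Ultra RNA kit. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

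The deposited values were whole-number counts per gene, not normalized, in 1 table for all 6 libraries. Per the series description, adapters were removed by the sequencing provider, and the authors aligned the reads to GRCh38 with STAR at its default settings and made counts per gene with Subread 2.0.3. The submitters' processing notes name STAR 2.7.10a and cutadapt 4.0, with no role given for the latter. Genes were tested with DESeq2 and called at p under 0.05, per the series description. The annotation release, the strand setting and the handling of read pairs and of reads with several matches were not given in the sources used here. The kit as named does not mark strand, so reads from overlapping genes, antisense partners and near-identical copies could not be told apart. Genes named for their p that overlap another gene of the table with coordinates on the same strand are named with that gene. Overlaps with antisense genes, with rows that lacked coordinates and with genes absent from the table were not checked. A count of 2 was more frequent than a count of 1, with 2226 values against 725 over the 6 libraries, which no source explains. If mates were counted separately, a fragment weighs up to 2 counts and the counting error is larger than the counts alone imply.

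The table held 19933 rows. Of these, 19696 carried Ensembl identifiers, and 19580 of them matched GENCODE v44 (GRCh38), which supplied coordinates, gene types and exon lengths. Symbols came from the deposited table where it gave them. A further 237 rows carried XLOC identifiers, of a kind that names assembled loci rather than annotated genes. They held 1.64% to 1.73% of the counts per library, were kept in the library sizes and tests, and were left out in an alternative. No column of values per sample was left unused. A total of 2631 rows were at 0 in all 6 libraries.

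Total counts per library ran from 33590857 to 44857062. A count of 0 allows up to 3 counts, which corresponds to 0.0677 to 0.0905 CPM on the TMM-scaled library sizes, and this floor covers counting error only. No 2 libraries held the same values. The smallest chi-square per degree of freedom between any 2 libraries was 26.4, above sampling noise, so no library was taken for a second copy of another. This does not show that the libraries came from separate cultures.

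Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were filtered with filterByExpr on the 2 groups, which left 13204 genes, and library sizes were scaled by TMM. A quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) compared sFlt-1 with control, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided unless said otherwise. CPM values are on TMM-scaled library sizes and are given as mean ± SD. Log2 fold changes are sFlt-1 minus control, so a negative value is lower with sFlt-1. Their standard errors were derived from the F statistic. The common biological coefficient of variation was 17.5%.

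A set of 26 gene lists was fixed before the data were examined. They covered VEGF ligands and receptors, leptin signalling, syncytiotrophoblast, cytotrophoblast and extravillous trophoblast genes, placental genes raised in preeclampsia, hypoxia, glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, the unfolded protein response, NRF2 targets, NF-kB and cytokine genes, interferon response, cell cycle, p53 targets, cholesterol synthesis, growth factor and MAPK response, TGF-beta and matrix, vasoactive factors, nutrient transporters, ribosomal proteins, markers of endothelial, fibroblast and immune cells, and replication histones with nuclear RNAs as a sign of RNA quality. The nuclear RNAs of the last list were not analysed here, and all its tested members are histones. Of the 827 symbols in the lists, 815 were found in the table. Lists were tested with camera (limma 3.58.1) on log2 CPM at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 26 lists. The same test with an estimated correlation and fry, a rotation test, were run beside it. Fry tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction, and neither compares a list with other genes. For each list the median deviation from the mean of the 6 libraries was also taken in every library. Groups were then compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3 libraries.

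The genes named were set by a rule fixed before the data were examined. It took LEP and the 10 VEGF ligands and receptors in every case. It added the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with a mean of at least 1 CPM and with all 3 treated libraries on the same side of all 3 controls. Since none passed, these places were filled with the genes of smallest p in each direction under the same conditions. It also took up to 4 members of each list with the smallest p, and the 5 genes with the smallest p overall. Genes with clone-based names were not named, nor were Y-linked genes and XIST.

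The procedure was tested on simulated data, with 200 changed genes in each of 5 simulations drawn from the means, library sizes and dispersions of these 13204 genes. The edgeR test recovered 31.6% of genes changed 1.5-fold, 69.6% of genes changed 2-fold and 90.0% of genes changed 4-fold, and 8.09% of its calls were false. Among genes with a mean count of 10 to 100 it recovered 0%, 2.69% and 47.0%, with 12.8% false calls. With no gene changed, edgeR called at most 3 genes, limma-voom at most 3 and DESeq2 at most 21 per simulation, and camera called 0 lists. Genes were simulated independently, so these 0 lists do not show how often lists of correlated genes would be called falsely. Under the same independence, a list shifted 1.2-fold was called in all 5 simulations with either correlation.

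Alternatives were DESeq2 1.42.0, limma-voom, size factors of the DESeq2 kind, upper quartile scaling and total counts in place of TMM, no low count filter, a stricter one (1 CPM in at least 3 libraries and a mean count of 50), no robust estimation, a replicate block, leaving out each library, p under 0.05 without adjustment, an adjusted p under 0.1, and a 1.5-fold minimum. Tables and plots were made with Python 3.11.15 and matplotlib 3.10.9.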

Results

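Gene expression was measured in BeWo trophoblast cells after 72 h with sFlt-1 at 1 ng/mL or with vehicle, in 3 libraries per group. sFlt-1 is the secreted form of VEGF receptor 1, which binds VEGF-A, VEGF-B and placental growth factor, and its level in maternal blood is raised in preeclampsia. Total counts were 34437390, 33804488 and 37228830 in control replicates 1 to 3 and 37071212, 44857062 and 33590857 in sFlt-1 replicates 1 to 3. Libraries of the same group correlated at 0.976 to 0.982 and libraries of different groups at 0.977 to 0.981 (Pearson's r of log2 CPM across genes, which are not independent replicates). Control replicate 3 stood apart, with 16567 genes above 0 against 14454 to 14709 in the others, and with 1.31% of its counts from mitochondrial transcripts against 0.859% to 1.07%.

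The series title names leptin production by trophoblasts and VEGF receptors 1 and 3, so LEP and the VEGF axis come first. LEP, which encodes the hormone leptin (ENSG00000174697, GRCh38 chromosome 7, 128241278 to 128257629, plus strand), was barely expressed. Its mean was 0.710 ± 0.140 CPM in control cells and 0.436 ± 0.0145 CPM in sFlt-1 cells (SD, n = 3 per group). This came from 23, 29 and 23 counts in the controls and 16, 20 and 14 counts with sFlt-1. All 3 sFlt-1 libraries lay below all 3 controls, an order that chance gives to 10% of genes in either direction. The log2 fold change was −0.70 with a standard error of 0.36, and the adjusted p of edgeR's quasi-likelihood test was 0.972, so the difference did not pass. The 95% interval of the log2 fold change ran from −1.53 to 0.14. At such counts a 2-fold change was recovered for only 2.69% of simulated genes.

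The leptin receptor and STAT3 were well covered. LEPR stood at 90.9 ± 4.54 and 82.6 ± 6.64 CPM, and STAT3, the transcription factor that signals below it, at 61.0 ± 2.38 and 55.0 ± 1.02 CPM (control and sFlt-1, SD, n = 3). LEPROT stood at 203 ± 79.7 and 98.5 ± 29.8 CPM. It overlaps LEPR on the same strand, so its reads are uncertain, and its value in control replicate 3 was 111 CPM, within the range of the sFlt-1 libraries up to 120 CPM. No member of the leptin list passed edgeR's test over all genes or adjusted over the list alone. The 12 tested members had a median log2 fold change of −0.14, with 5 above 0 and 7 below. The list did not pass camera's test (adjusted p = 0.113, and adjusted p = 0.937 with an estimated correlation). Fry's mixed test, for change in either direction, gave an adjusted p of 0.00272 for this list, the only call of that kind among the 26. This call was not examined in the simulated data or with a library left out. An exact permutation test of the library medians gave p = 0.1 for this list, the smallest p it can give.

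Of the VEGF receptors, FLT4 (VEGF receptor 3, chromosome 5, 180601506 to 180649624, minus strand) was the most abundant, at 44.9 ± 2.45 CPM in control and 53.2 ± 4.22 CPM in sFlt-1 cells (SD, n = 3). All 3 sFlt-1 libraries lay above all 3 controls. Its log2 fold change of 0.24 had a standard error of 0.09. The unadjusted p was 0.0272 in edgeR and the adjusted p was 0.972, so FLT4 did not pass. FLT1 (VEGF receptor 1, chromosome 13, 28300346 to 28495145, minus strand), the gene whose soluble product was added to the cells, was low, at 1.31 ± 0.469 and 1.30 ± 0.713 CPM. KDR (VEGF receptor 2) had 0 counts in all 6 libraries, which allows up to 0.0905 CPM. The co-receptor NRP1 stood at 0.917 ± 0.143 and 0.569 ± 0.134 CPM with a log2 fold change of −0.69, and NRP2 at 0.650 ± 0.276 and 0.432 ± 0.256 CPM with −0.61, and neither passed. Both had their highest count in control replicate 3, at 40 and 35, the library with the most genes above 0. Whether background reads raised these control values was not tested.

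The ligands were dominated by PGF and VEGFA. PGF, which encodes placental growth factor, stood at 326 ± 33.6 and 364 ± 23.4 CPM, a log2 fold change of 0.16 with a standard error of 0.09. VEGFA stood at 197 ± 18.1 and 197 ± 24.9 CPM, and the 95% interval of its ratio was 0.840 to 1.19. VEGFB stood at 10.9 ± 1.01 and 11.2 ± 0.454 CPM (SD, n = 3). VEGFC had at most 3 counts and VEGFD at most 2 in any library, so neither was tested. None of the 7 tested members of this list passed edgeR's test over all genes, and none passed adjusted over the list alone. At p under 0.05 without adjustment, FLT4 was the 1 member counted, by edgeR and by DESeq2. The list as a whole had a median log2 fold change of −0.00094 against a mean of −0.12, and camera gave an adjusted p of 0.984.

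**Figure D1:**
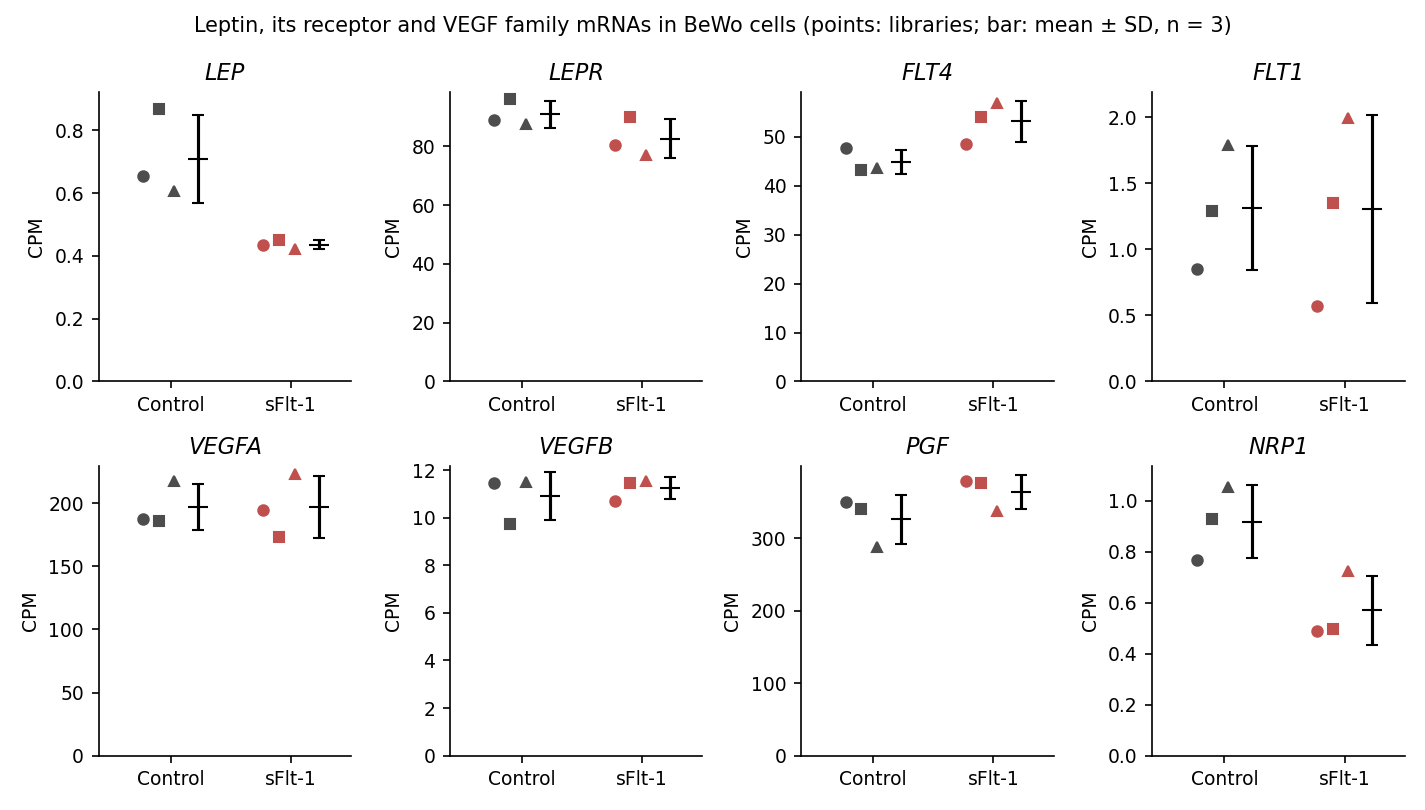
CPM (vertical axes, from 0) of 8 genes of the leptin and VEGF axis in 3 control and 3 sFlt-1 libraries, with each library as a point (circle, square and triangle for replicates 1, 2 and 3) and the mean ± SD as a bar. The LEP points of the sFlt-1 group lie below those of the control group and the FLT4 points above, while the FLT1 and VEGFA points overlap.

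Across the transcriptome, no gene passed edgeR's test. Of 13204 tested genes, 0 had an adjusted p under 0.05 in edgeR. At p under 0.05 without adjustment edgeR counted 583 genes, 313 higher and 270 lower with sFlt-1. A share of 0.05 of the tested genes is 660.2. The 5 simulations with no gene changed gave 575 to 643 such genes, a range that holds the observed count. DESeq2 called 25 genes at its adjusted p and 584 without adjustment, and limma-voom called 4. Where no gene was changed in simulations of these libraries, DESeq2 called up to 21. The median 95% interval of a gene's log2 fold change extended 0.30 to either side, a 1.24-fold difference.

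The gene nearest the threshold was STX16, which encodes syntaxin 16, a SNARE protein of transport between endosomes and the trans-Golgi network. It stood at 47.3 ± 4.47 CPM in control and 17.9 ± 2.53 CPM in sFlt-1 cells (SD, n = 3), a log2 fold change of −1.40 with a standard error of 0.13. Its adjusted p was 0.0523 in edgeR's test, and it was past 0.05 in DESeq2 and limma-voom. STX16 lies on chromosome 20, 58651272 to 58679526, plus strand. ATP23, which encodes a mitochondrial inner membrane protease, had 0 counts in all 3 control libraries and 60 to 68 counts with sFlt-1, or 1.68 ± 0.281 CPM. That is at least 19.8-fold higher against 3 counts in each control library, a bound that assumes 1 count per fragment and, like those below, would be lower with 2. ZBTB12, which encodes a zinc finger protein, likewise had 0 counts in the controls and 25 to 41 with sFlt-1, at least 10.1-fold higher on the same floor. TLCD2 went the other way, with 47 to 75 counts in the controls and 0 in all 3 sFlt-1 libraries, at least 21.4-fold lower. Their adjusted p values in edgeR were 0.0941 for ATP23 and TLCD2 and 0.381 for ZBTB12, and all 3 were past 0.05 in DESeq2 and limma-voom. Counts of exactly 0 beside well-covered libraries also appeared in 6 genes whose 3 empty libraries came from both groups. Another 11 genes were at 0 in 1 library and at 100 or more counts in the other 5. BDP1, for example, had 0 counts in control replicate 1 and 1489 to 2240 in the others. A 0 in this table can therefore be more than counting error, and the fold bounds above do not cover that.

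None of the other genes with the smallest p passed edgeR's test. DESeq2 called all of those named here but CLEC11A, ANKRD13C, NUP62 and ZNF569, and limma-voom called none of them. PRELID1, which carries phosphatidic acid between the mitochondrial membranes, stood at 119 ± 3.42 CPM in control and 177 ± 19.3 CPM with sFlt-1. CNNM3, SERF2, INPP4A, CLEC11A and ANKRD13C had log2 fold changes between 0.34 and 0.50, and WDR37 had 0.81. DIXDC1, a component of Wnt signalling, had 1.22, and SULT1A4, a sulfotransferase with a near-identical copy in SULT1A3, had 1.26. On the lower side, CCDC69 stood at 8.92 ± 0.491 and 3.69 ± 0.964 CPM and C19orf54 at 5.32 ± 0.549 and 2.28 ± 0.547 CPM (SD, n = 3). NCBP3 and RNMT, both of which act on capped mRNA, had log2 fold changes of −0.53 and −0.59. NUP62, a protein of the nuclear pore, had −0.48, ZNF569 had −0.72 and the phospholipid flippase ATP11A had −0.79. WDR6 had −1.76, with control values from 758 to 2000 counts per library. SERF2, NUP62 and WDR6 overlap HYPK, IL4I1 and P4HTM on the same strand. On total counts without TMM, their log2 ratios were 0.35, −0.50 and −1.78 alone and 0.34, −0.50 and −1.78 summed with these partners. ANKHD1 and the readthrough gene ANKHD1-EIF4EBP3, which share exons, had 0.50 and −0.69, and reads of the shared exons cannot be assigned to either with certainty. The readthrough gene also overlaps EIF4EBP3 on the same strand.

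**Figure D2:**
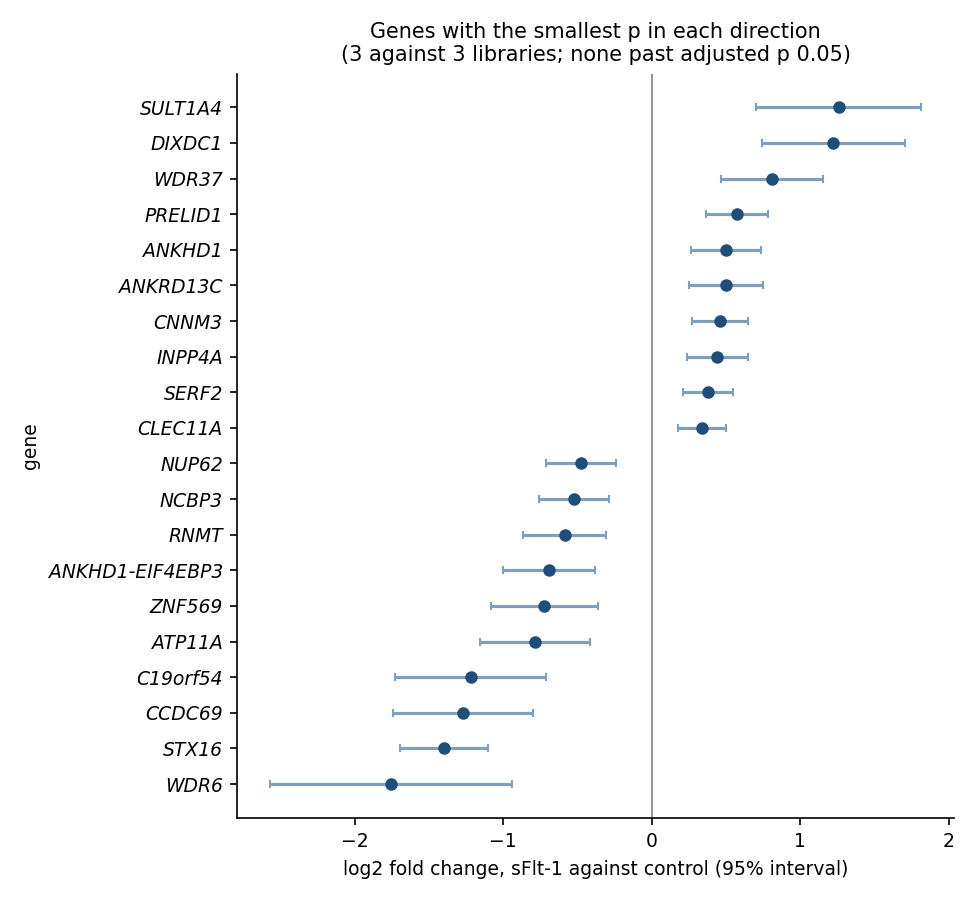
Log2 fold change (horizontal axis, sFlt-1 against control) of the 10 genes with the smallest p in each direction, among those with a mean of at least 1 CPM and separated groups, with edgeR estimates from 3 against 3 libraries as points and 95% intervals, not adjusted for the choice of genes, as bars. Estimates run from −1.76 for WDR6 to 1.26 for SULT1A4, and no gene passed the adjusted threshold in edgeR's test.

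Among the 26 lists, 5 passed camera's test at the preset correlation, and 0 passed with an estimated correlation or with fry. Cytosolic ribosomal protein mRNAs were higher with sFlt-1, with 70 of 77 members above 0 and a median log2 fold change of 0.13 (camera, adjusted p = 3.19e-08, and adjusted p = 0.937 with an estimated correlation). RPS28 stood at 824 ± 71.1 and 998 ± 30.8 CPM and RPS13 at 833 ± 35.9 and 969 ± 8.70 CPM (control and sFlt-1, SD, n = 3). RPL29 stood at 1071 ± 91.6 and 2165 ± 885 CPM, with 42635 counts in sFlt-1 replicate 1 against 112558 and 92845 in replicates 2 and 3, and DESeq2 called it. Replication histones, whose transcripts mostly lack poly(A) tails, were higher as well, with 30 of 31 members above 0 and a median of 0.13 (adjusted p = 2.59e-06, and adjusted p = 0.937 with an estimated correlation). H2BC7 stood at 65.9 ± 1.89 and 76.2 ± 4.48 CPM and H3C7 at 264 ± 22.4 and 308 ± 14.2 CPM, and such histone genes have near-identical copies.

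Nuclear genes of oxidative phosphorylation followed the same direction, with 56 of 71 members above 0 and a median of 0.08 (camera, adjusted p = 0.00175, and adjusted p = 0.937 with an estimated correlation). The complex I subunit NDUFS7 stood at 45.0 ± 1.89 and 53.3 ± 2.05 CPM, and NDUFB4, of the same complex, at 75.0 ± 6.88 and 90.6 ± 6.24 CPM. The 13 mRNAs encoded by mitochondrial DNA were all lower, with a median of −0.25 (adjusted p = 0.00438, and adjusted p = 0.937 with an estimated correlation). ND4 stood at 726 ± 193 and 571 ± 95.5 CPM and the mitochondrial COX2, cytochrome c oxidase subunit II, at 1037 ± 220 and 865 ± 92.7 CPM.

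Syncytiotrophoblast genes, which mark the fused and hormone-secreting layer of the placenta, were also higher, with 25 of 34 tested members above 0 and a median of 0.17 (camera, adjusted p = 0.00731, and adjusted p = 0.937 with an estimated correlation). The stress-responsive cytokine GDF15 stood at 915 ± 90.0 and 1116 ± 38.3 CPM (control and sFlt-1, SD, n = 3). CYP11A1, which starts steroid hormone synthesis, had a log2 fold change of 0.24 with a standard error of 0.09, and the transcription factor OVOL1 stood at 87.0 ± 6.78 and 100.1 ± 4.02 CPM. The placental lactogen gene CSH2 stood at 11.5 ± 0.513 and 15.4 ± 2.45 CPM, and its reads are shared with near-identical paralogs. The 4 tested retroviral envelope genes of this list, named after their values were seen, all had log2 fold changes below 0 and did not pass: ERVW-1 (syncytin-1) and ERVFRD-1 (syncytin-2), which mediate cell fusion, had −0.24 and −0.21, and ERVV-1 and ERVV-2 had −0.20 each. None of the members of these 5 lists passed edgeR's test over all genes, and none passed adjusted over the list alone.

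In all 5 lists control replicate 3 lay farthest from the mean of the libraries. Its median deviation from the mean of the 6 libraries was −0.21 for ribosomal proteins, −0.18 for oxidative phosphorylation, −0.21 for histones, −0.18 for syncytiotrophoblast genes and 0.49 for mitochondrially encoded mRNAs. Control replicate 2 lay on the side of the sFlt-1 libraries for ribosomal proteins (0.11), oxidative phosphorylation (0.10) and histones (0.07). For mitochondrially encoded mRNAs the sFlt-1 libraries lay on both sides of 0, at −0.18, −0.27 and 0.11 in replicates 1 to 3, and control replicate 2 lay at −0.17. An exact permutation test of the library medians gave p = 0.4 for ribosomal proteins, oxidative phosphorylation and mitochondrially encoded mRNAs, 0.3 for histones and 0.1 for syncytiotrophoblast genes, where 0.1 is the smallest p that 3 against 3 libraries allow. Without control replicate 3, 2 lists passed, ribosomal proteins with a median of 0.06 and histones with 0.07. The medians of the others were then 0.02 for oxidative phosphorylation, 0.11 for syncytiotrophoblast genes and −0.03 for mitochondrially encoded mRNAs. Without sFlt-1 replicate 1 or sFlt-1 replicate 2, the mitochondrially encoded mRNAs did not pass either, with medians of −0.21 and −0.15, and without sFlt-1 replicate 3 their median was −0.38. Without control replicate 2 the medians were larger, at 0.22 for ribosomal proteins, 0.16 for oxidative phosphorylation, 0.20 for histones and −0.38 for mitochondrially encoded mRNAs.

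**Figure D3:**
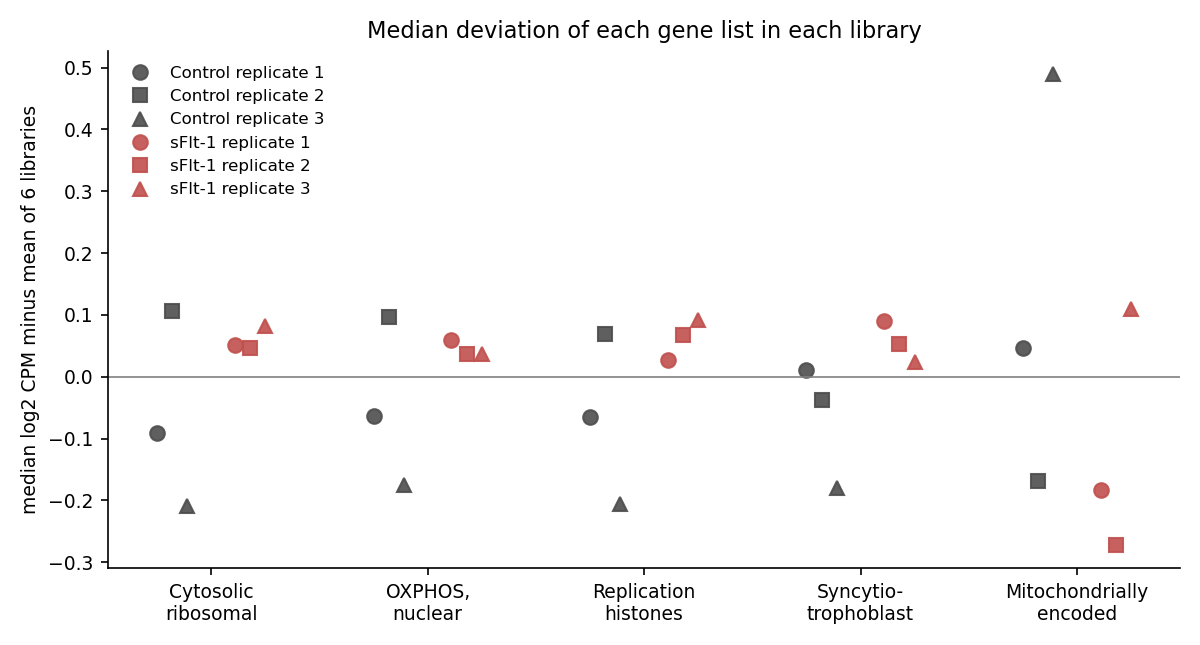
Median deviation of the genes of 5 lists in each library (vertical axis, log2 CPM minus the mean of the 6 libraries), with control libraries in grey, sFlt-1 libraries in red and circle, square and triangle for replicates 1, 2 and 3. Control replicate 3 lies farthest from 0 in all 5 lists, at −0.21 for ribosomal proteins and 0.49 for mitochondrially encoded mRNAs.

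The other trophoblast lists did not pass. Cytotrophoblast genes had a median log2 fold change of 0.0028 over 22 tested members (camera, adjusted p = 0.807), with the epithelial cadherin CDH1 at 1246 ± 61.6 and 1117 ± 33.7 CPM and the keratin KRT8 at 2611 ± 215 and 3005 ± 303 CPM (control and sFlt-1, SD, n = 3). Extravillous trophoblast genes had a median of 0.02 over 17 members (adjusted p = 0.807), with the transcription factor ASCL2 at 86.0 ± 4.29 and 100.5 ± 4.92 CPM. Placental genes raised in preeclampsia had a median of 0.03 over 23 members (adjusted p = 0.829), with 14 above 0 and 9 below. LEP and SASH1, with the smallest p of this list, were lower, with log2 fold changes of −0.70 and −0.15. Next came the protease HTRA4 at 281 ± 25.8 and 315 ± 23.1 CPM and the lipid droplet protein PLIN2 at 2147 ± 70.3 and 2334 ± 104 CPM. Nutrient transporters had a median of −0.02 over 26 members and vasoactive factors 0.03 over 15 members (adjusted p = 0.889 and 0.807). Adrenomedullin (ADM), a vasodilator peptide of the second list, stood at 45.7 ± 1.47 and 54.0 ± 5.42 CPM. RAMP2, with the smallest p of that list, was lower, at 0.829 ± 0.159 and 0.420 ± 0.0824 CPM.

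The lists of markers of other cell types did not pass camera's test. Endothelial markers, included because endothelial cells were cultured in the same study, had a median log2 fold change of −0.03 and a mean of 0.04 over 9 tested members, and camera's direction was up (adjusted p = 0.807). BeWo cells expressed some of them, with EGFL7 at 54.5 ± 4.38 and 64.3 ± 4.51 CPM (control and sFlt-1, SD, n = 3). Fibroblast markers had a median of −0.05 over 6 members (adjusted p = 0.889), with FBLN1 at 346 ± 47.5 and 357 ± 42.3 CPM. Immune markers had a median of 0.05 and a mean of −0.08 over 6 members (adjusted p = 0.947), and camera's direction was down. ITGAM, an integrin of myeloid cells, had a log2 fold change of 0.07 with a standard error of 0.17.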

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

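Leaving out XLOC rows and correcting for exon length were chosen after seeing the data, and the other alternatives before. The count of genes past the threshold, 0 by edgeR with TMM, also stayed at 0 with RLE size factors, total counts, the stricter filter, no robust estimation, no XLOC rows and a 1.5-fold minimum. It was 1 with upper quartile scaling (STX16), 3 with no low count filter (STX16, ATP23 and TLCD2), 3 at an adjusted p under 0.1, 4 with limma-voom and 25 with DESeq2. Without adjustment it was 583 in edgeR and 584 in DESeq2. Leaving out 1 library gave 0 to 5 genes. It was 3 without control replicate 1 or sFlt-1 replicate 3, 5 without control replicate 2 or sFlt-1 replicate 1, and 1 without sFlt-1 replicate 2. The genes differed between these fits. STX16 passed only without control replicate 2 or sFlt-1 replicate 3, and ATP23 and TLCD2 passed in none of them. The count of VEGF ligands and receptors was 0 under the other alternatives and 1 at an unadjusted p, in edgeR and in DESeq2. LEP had a negative log2 fold change under every alternative that tested it, from −0.80 to −0.53 when 1 library was left out. The stricter filter left LEP untested. The count of lists, 5, became 0 with an estimated correlation, 0 with fry, 2 after the exon length correction and 7 with no low count filter, and leaving out 1 library gave 2 (without control replicate 3) to 6. The medians next given are of differences in mean log2 CPM rather than of edgeR's log2 fold changes. The exon length correction moved those of the lists that no longer passed from 0.17 to 0.15 for syncytiotrophoblast genes, from 0.10 to 0.08 for oxidative phosphorylation and from 0.13 to 0.06 for histones (camera, adjusted p = 0.128, 0.128 and 0.0764). The cause of these moves was not tested, though leaving out a library also leaves fewer samples. 3 genes near 0 changed sign. The VEGFA log2 fold change became 0.0024 with no low count filter and ran from −0.0998 to 0.0828 when 1 library was left out, the VEGFB log2 fold change from −0.0295 to 0.0842 and the FLT1 log2 fold change from −0.44 to 0.35. Of all values of named genes under an alternative, 1054 kept their direction and side of the threshold, 7 changed sign and 32 passed. For lists, 341 values kept both, 18 no longer passed and 3 newly passed.

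The labels do not say whether replicate numbers pair the samples. Same-numbered libraries deviated together at r = −0.05, 0.02 and 0.13, too few values to show or exclude pairing. With a replicate block, 0 genes passed, 829 had an unadjusted p under 0.05, 5 lists passed and LEP had −0.69.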

Other observations

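The test of counts missing in single libraries was chosen after the 3 genes it concerns had been seen, and its bound was tightened after its result, which the bound first set would have counted for that explanation. The tests on canonical transcript length were chosen after the result on exon length, and the other tests before their results, though the endothelial result met a bound set beforehand against that explanation and was left open because it lay within the spread of the random sets. Apart from the splits of the libraries, the tests are on patterns noticed in the same data.

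Stress and growth lists did not pass camera's test. Genes of the unfolded protein response had a median log2 fold change of −0.04 over 43 members (adjusted p = 0.807), with HERPUD1, a factor of protein degradation at the endoplasmic reticulum, at 177 ± 27.4 and 129 ± 20.7 CPM and the chaperone CRELD2 at 12.3 ± 0.768 and 9.43 ± 1.16 CPM (control and sFlt-1, SD, n = 3). NRF2 targets had a median of 0.07 and a mean of −0.09 over 26 members, and camera's direction was up (adjusted p = 0.434). NFE2L2, which encodes NRF2 itself, stood at 86.2 ± 4.66 and 44.5 ± 25.2 CPM, with 2715, 1358 and 969 counts in sFlt-1 replicates 1 to 3. Targets of p53 had a median of 0.06 over 31 members (adjusted p = 0.113), and GADD45B stood at 3.99 ± 0.515 and 5.38 ± 0.541 CPM. Cell cycle genes had a median of −0.0024 over 60 members (adjusted p = 0.947, with camera's direction up and fry's down), with the cyclin CCNE2 at 5.23 ± 0.220 and 3.89 ± 0.183 CPM. Growth factor and MAPK response genes had a median of 0.01 and a mean of −0.09 over 29 members, and camera's direction was down (adjusted p = 0.889).

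Inflammatory and metabolic lists did not pass either. NF-kB and cytokine genes had a median of 0.03 over 16 members (adjusted p = 0.807) and interferon genes −0.02 over 28 members (adjusted p = 0.889). Hypoxia genes had a median of 0.01 over 37 members (adjusted p = 0.534), with CITED2 at 420.1 ± 11.1 and 478 ± 22.2 CPM. BNIP3L of the same list was lower, at 260.6 ± 9.87 and 167 ± 75.8 CPM. Glycolysis had a median of 0.04 over 21 members (adjusted p = 0.434), with GAPDH at 7520.2 ± 627 and 6631 ± 591 CPM. PFKM and ENO1, with smaller p, were higher, at 48.7 ± 3.89 and 55.8 ± 4.47 CPM and at 1306 ± 63.6 and 1475 ± 141 CPM. Cholesterol and lipid synthesis had 0.02 over 33 members (adjusted p = 0.947), and TGF-beta and matrix genes −0.02 over 34 members (adjusted p = 0.829).

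The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes in edgeR and the highest other split 8, and that 10 of the 10 splits gave at least as many says nothing, since no count is below 0. For genes at an unadjusted p these values were 583 and 1575, with 4 splits as large. For DESeq2 they were 25 and 146, with 6 splits as large, and for lists 5 and 7, with 5 splits as large. The split with 146 genes set control replicates 1 and 3 and sFlt-1 replicate 3 against the rest. It was picked as the highest after the counts were seen, and what lies behind it was not tested.

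The genes with the smallest p included a readthrough gene and genes with counts of 0 in a whole group. Of the 23 genes named for their p, 21.7% overlapped another gene of the table on the same strand, against 8.72% of the other tested genes, an odds ratio of 2.91 with a 95% interval of 0.843 to 8.15 (Fisher's exact test, two-sided p = 0.0451), which met the criterion set beforehand although the interval includes 1, and 2 of the 5 overlapping genes were the ANKHD1 pair. On total counts without TMM, the log2 ratio summed over ANKHD1 and ANKHD1-EIF4EBP3 was −0.21, from 0.47 and −0.72 apart. Reads moved between them may therefore account for this pair. Summed with EIF4EBP3, which it also overlaps, ANKHD1-EIF4EBP3 had −0.67. Summing with the overlapping gene left SERF2 at 0.34, NUP62 at −0.50 and WDR6 at −1.78, so reads counted for these partners instead do not account for these 3. Reads left uncounted because they matched both genes would not return in a sum. Antisense genes, rows without coordinates and genes absent from the table were not tested. The table was mostly protein-coding, with 60 lncRNA rows of 19933. Genes with no overlapping partner here, STX16 among them, may therefore still overlap a gene that was not checked. A total of 57 genes were at 0 in 1 to 5 libraries and at 20 or more counts in the others, and of the 9 at 0 in exactly 3 libraries, 33.3% had them in 1 whole group, where chance gives 10% (exact binomial test, one-sided p = 0.0530). Counts that go missing in single libraries regardless of group could therefore also yield ATP23, TLCD2 and ZBTB12, and 9 genes are too few to tell this from an effect of sFlt-1.

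Ribosomal, respiratory chain and histone mRNAs, all short, had medians above 0 with sFlt-1 that passed camera only at the preset correlation (adjusted p = 0.937 for each with an estimated correlation), and over genes outside these lists log2 fold change was lower at greater exon length (Spearman's rho = −0.193 across 12740 genes, which are not independent). A loess correction on total exon length left 0.920 of the ribosomal median, and a share of 0.8 or more had been set beforehand as evidence against a length bias, but that length is a poor measure here, with a median of 3228 bases for ribosomal genes against 869 for their canonical transcripts. Corrected on canonical transcript length, 0.661 of the ribosomal, 0.589 of the respiratory chain and 0.573 of the histone median was left, and camera at the preset correlation then gave adjusted p of 6.40e-04, 0.326 and 0.0137, so a length bias may hold part of the pattern and its full share stays open. Mitochondrially encoded mRNAs, with a median of 784 bases, are as short but were lower. The same correction moved the median of their differences in mean log2 CPM from −0.23 to −0.29 (camera, adjusted p = 6.40e-04), so a length bias does not account for them. Without control replicate 3 the ribosomal median kept 0.478 of its size and without control replicate 2 it was 1.75 times its size, so that these libraries, a length bias and an effect of sFlt-1 cannot be told apart with 3 libraries per group.

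Control replicate 3 had low counts in many genes that were at 0 in the other libraries, 1411 such genes with a median of 3 counts, against 68 to 92 genes found in only 1 of the other libraries. Library size is argued against as the source, since after thinning to the smallest total this library still had 1876 more genes above 0 than the next. RNA from endothelial cells, which were cultured in the same study, stays open, since the median count of 1 over the 12 of 22 markers low elsewhere was at the 39.8th percentile of 10000 random sets matched on exon length, well within their spread, and while ROBO4 had 19 counts, ERG, CLDN5 and SOX17 had 3 and SOX18 had 2 in this library and 0 in the others, KDR, EMCN, CD34 and ECSCR had 0 in all 6. Counts rose with exon length over the 4042 genes at 0 elsewhere (Spearman's rho = 0.362 across genes), which is consistent with background reads spread in proportion to exon length. The design gives no biological explanation for 1 control library, so none was tested.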
